A study of Mus musculus with 137 samples.

How the data were processed

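RNA of mouse bone marrow-derived macrophages was profiled by Smart-Seq2, which primes with oligo-dT, in paired reads and without molecular barcodes or strand information. Per the labels, marrow of mice aged 7 weeks was cultured for 7 days with M-CSF at 20 ng/ml and left untreated or given LPS at 100 ng/ml and IFN-gamma at 100 ng/ml for 6 h or 24 h. The authors deposited 1 table of raw counts per cohort, as counts per gene symbol and library, made with TopHat and HTSeq on genome build mm10 per the submitters' processing notes, with no versions given. Values are whole numbers, and the same 34573 symbols stand in each table, of which 29042 (84.0%) are found in GENCODE vM21, used here for names, positions and GC content. Because reads are unstranded and the annotation is not stated, reads of overlapping or near-identical genes cannot be assigned beyond what the counts give.

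The 54 libraries of KO1 are 3 culture numbers per genotype (S33 to S35 for WT and S36 to S38 for KO), each with 3 repeats at each time. Repeats were summed to 18 units, so that n is 3 per group. KO2 has 8 libraries per group (7 in WT at 24 h) and KI has 6, each taken as a unit, and the labels do not say whether these came from separate mice or cultures. Counts per library ran from 1898574 to 6579185 in KO1, 1448218 to 15627379 in KO2 and 3574158 to 11786453 in KI, and none of the 137 libraries was under the minimum of 250000. No pair of libraries of a group looked like a copy or a resequenced library, with the smallest chi-square per degree of freedom at 2.79 over 467 pairs. The labels of 2 samples conflict between fields, and an alternative leaves them out.

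Genes were filtered by filterByExpr and scaled by TMM in edgeR 4.0.16 (R 4.3.3), and each cohort had 1 quasi-likelihood fit with a mean for each of its 6 groups. Contrasts were mutant against WT at each time, WT at 6 h and 24 h against 0 h, and genotype by time as a joint test of both differences. The difference of 2 cohorts' genotype effects came from a joint fit of both. P values were adjusted by Benjamini-Hochberg over all genes tested, and the standard error is the absolute log2 fold change over the square root of F. CPM values of single libraries use all counts in genes, without TMM. Before the data were examined, 34 function lists and 13 marker lists with 1030 genes were fixed, 4 of which were not found. They were tested with camera in limma 3.58.1, at a preset correlation of 0.01 and at an estimated one, and with fry, adjusted within a comparison over function lists and marker lists separately. For function lists alone, camera at the preset correlation gave 212 list calls over all comparisons, at an estimated correlation 81, and fry, which does not compare a list with other genes, 250. Genes are named by a rule fixed at the same time: Becn1 and Lyz2 throughout, the 8 highest and 8 lowest log2 fold changes among calls with a mean log2 CPM of at least 3 in each genotype comparison, and up to 3 called members of smallest adjusted p per list, or any where a list has 5 or fewer calls. For the WT time course it takes the 10 highest and 10 lowest among genes called in 1 direction in all cohorts, for genotype by time the 5 smallest p, and between cohorts the genes called alike in KO1 and KO2 and the 5 smallest p of each difference. The transcript 1810033B17Rik falls under the last part. A member of the ribosomal protein list is not reported here.

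To test the fits, negative binomial counts were simulated from the fitted means and dispersions of each cohort, with 200 genes changed in the mutant at 24 h: 32.8%, 85.1% and 82.1% of genes changed 2-fold and 87.9%, 97.0% and 97.0% of those changed 4-fold were called in KO1, KO2 and KI. Whether replicate numbers pair libraries across groups was checked by the correlation of their deviations from the group means: KO1 WT cultures correlated best with their own number in 3 of 3 between 0 h and 6 h (r of 0.255 to 0.619) and in 1 of 3 between 0 h and 24 h (r of -0.00640 to 0.374), and KO2 and KI numbers did not pair throughout. The fits were set without a block in advance, with the block as an alternative. Alternatives fixed in advance were DESeq2 1.42.0, its size factors in edgeR, no filter beyond 1 count, only the 2 groups compared, the replicate number as a block, conflicting samples left out, each culture left out in KO1, single libraries as units in KO1, voom with duplicateCorrelation (consensus 0.0872) and the estimated correlation for lists. Sex chromosome genes left out, replicate numbers summed in threes (KO2) or pairs (KI), F121A 0 h replicate 5 left out, a library preparation score as covariate, the GC trend of each library removed, KO1 culture numbers paired across genotypes and resting KO1 libraries or cultures left out of the mixing test were chosen after seeing the data. The preparation score is a library's position on the first component of the deviations between repeats of a KO1 culture. The labels do not say in what these repeats differ, so its name is a presumption. The score also follows stimulation: its WT means in KO1, KO2 and KI were 1.06, 1.08 and 1.29 at 0 h and -1.09, -0.450 and -0.626 at 24 h. Across times it thus does not measure preparation alone. Refits that left out part of the KI WT 24 h libraries by their level of Tnf, and a block of KO1 culture pairs crossed with time, were tried and dropped: the former picks samples by an outcome, and for the latter the labels give no pairs. Where nothing says that samples came from separate cultures or mice, as in KO2 and KI, p values measure only the spread between these samples, which may be technical. Raw reads and protein data were not analysed here.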

Results

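Bone marrow-derived macrophages of 3 mouse cohorts were compared at rest (0 h) and after 6 h and 24 h with LPS and IFN-gamma. In cohorts KO1 and KO2 a floxed Beclin1 gene was crossed to LysM-Cre (KO) and compared with Cre-negative cells (WT). In cohort KI both Beclin1 alleles carried the F121A change, and littermates served as WT. The series holds 137 libraries, 54 in KO1, 47 in KO2 and 36 in KI, with median counts in genes of 3259979.5, 4914865 and 7765480.5 per library. Log2 fold changes are mutant over WT with the standard error after the ± sign, and a gene is called at an adjusted p under 0.05 over all genes tested.

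Becn1, which encodes the autophagy and endosomal protein Beclin1, was lower in both knockout cohorts at every time and did not pass the test in the F121A macrophages. In KO2 its log2 fold change was -3.28 ± 0.15 at rest, -3.31 ± 0.16 at 6 h and -2.63 ± 0.16 at 24 h (adjusted p = 6.1e-25, 2.2e-24 and 2.2e-19), lower in 8 of 8 KO libraries each time. In KO1 it was -1.51 ± 0.20, -1.52 ± 0.21 and -1.41 ± 0.20 (adjusted p = 0.00452, 0.00784 and 0.0166), lower in 3 of 3 KO cultures each time. Resting KO cells still held 18.8 (SD 8.35) CPM of Becn1 in KO1 and 4.87 (SD 1.53) in KO2, against 50.6 (SD 9.31) and 42.5 (SD 5.76) in WT, and 48.6 (SD 10.9) in F121A against 49.1 (SD 5.53) in littermates. The F121A log2 fold changes were -0.08 ± 0.09, 0.05 ± 0.09 and -0.04 ± 0.09, within the spread between replicates, with adjusted p = 0.855, 0.804 and 0.881. Lyz2, the lysozyme gene whose locus carries the LysM-Cre driver, fell in KO2 (-1.52 ± 0.12, -1.71 ± 0.12 and -1.31 ± 0.12 at the 3 times) and did not pass the test in KO1 (-0.77 ± 0.41, -0.96 ± 0.41 and -1.11 ± 0.41). In KI it fell at 24 h (-0.52 ± 0.09) and was -0.29 ± 0.09 and -0.13 ± 0.09 at 0 h and 6 h, not called. Counts are per gene, so a deleted exon lowers a Becn1 count only through reads that are lost or RNA that is unstable. The KO1 call of Becn1 is lost at 0 h without culture S33, S34, S36 or S38 (adjusted p = 0.0687, 0.0813, 0.0528 and 0.0782), at 6 h without S33, S34, S35 or S38 (0.0733, 0.122, 0.0639 and 0.148), and at 24 h without S33, S34, S36 or S38 (0.258, 0.181, 0.106 and 0.284), always with the same direction. With only the 2 groups compared it is lost at 0 h and 6 h (adjusted p = 0.404 and 0.315).

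**Figure D1:**
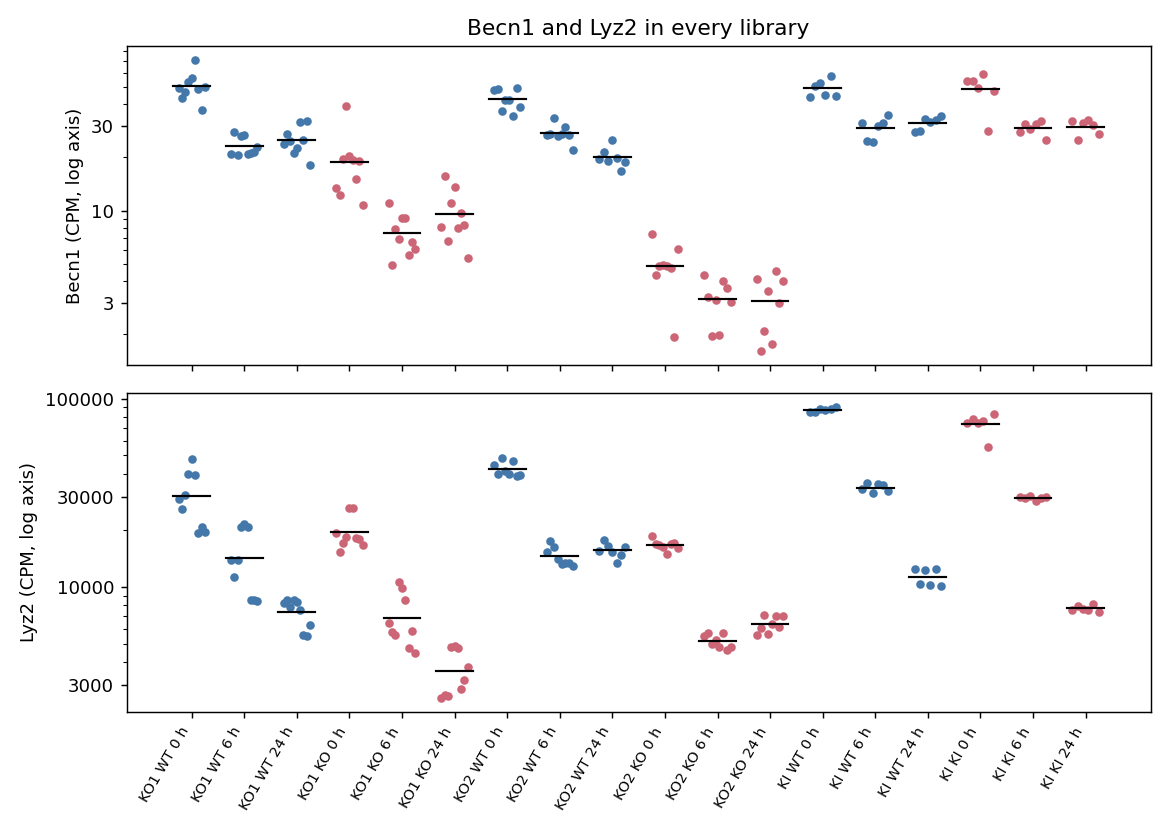
Becn1 (upper panel) and Lyz2 (lower panel) in CPM on a log axis. Each point is 1 library, bars are group means, blue is WT and red is KO or KI. Becn1 lies lower in the KO groups of KO1 and KO2, and the KI groups overlap with their WT.

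WT macrophages of all 3 cohorts switched on inflammatory and interferon genes within 6 h. Of 10612 genes tested in every cohort, 2317 rose and 2870 fell in all 3 at 6 h, and 62 were called in all 3 with mixed directions. Among the strongest to rise, as log2 fold change from the lowest to the highest cohort, were Cxcl9 (11.48 to 15.33), Il12b (12.99 to 13.10), Il6 (12.03 to 12.85), Ptgs2 (11.27 to 12.57), Il1a (11.59 to 12.45) and Nos2 (11.03 to 14.61): an interferon-induced chemokine, 3 cytokine genes, the inducible cyclooxygenase and the inducible nitric oxide synthase. Gbp5, Il27, Serpina3f and Serpina3g were among them too (Gbp5 (9.94 to 13.32), Il27 (10.45 to 13.90), Serpina3f (11.17 to 12.98) and Serpina3g (10.18 to 13.67)). The strongest to fall included Tmem37 (-7.89 to -5.55), Cd300lb (-6.25 to -5.05), Sesn1 (-7.07 to -5.77), Cx3cr1 (-7.11 to -4.88) and Cerk (-5.93 to -5.11), with Cx3cr1 the fractalkine receptor and Cerk a ceramide kinase. Inflammatory cytokines and NF-kB targets rose as a whole: 40 of 40 in KO1, 38 of 38 in KO2, 37 of 37 in KI (camera adjusted p = 4.1e-26, 3.6e-33, 9.8e-24, adjusted p = 0.0262, 1.3e-10, 0.00172 with an estimated correlation, cohorts in the same order). Type I interferon-stimulated genes rose in 34 of 41 in KO1, 40 of 40 in KO2, 41 of 41 in KI (camera adjusted p = 6.4e-11, 9.4e-32, 2.5e-27, adjusted p = 0.459, 5.6e-04, 0.00143 with an estimated correlation). Interferon-gamma GTPases and targets rose in 32 of 35 in KO1, 35 of 35 in KO2, 35 of 35 in KI (camera adjusted p = 2.8e-19, 6.5e-29, 5.3e-25, adjusted p = 0.155, 4.8e-04, 0.00172 with an estimated correlation). In autophagy machinery 18 of 37 in KO1, 21 of 36 in KO2, 20 of 37 in KI fell at 6 h and 4 of 37 in KO1, 7 of 36 in KO2, 8 of 37 in KI rose, with Atg7 (-2.41 ± 0.25, -2.22 ± 0.14 and -2.75 ± 0.15) among the former. The list passed the test in KO1 alone and in no cohort with an estimated correlation (camera adjusted p = 0.0210, 0.0709, 0.0968, adjusted p = 0.451, 0.0630, 0.139 with an estimated correlation). At 24 h, 1952 genes were higher and 1425 lower in all 3 cohorts, and 106 were called with mixed directions. The strongest to rise were Nos2 (10.72 to 14.50), Gbp4 (10.31 to 13.88), Saa3 (7.58 to 14.43), Upp1 (9.84 to 12.39), Tgtp1 (9.70 to 11.67), Il1b (9.03 to 11.54) and Iigp1 (7.26 to 13.05), and the strongest to fall included Ptgs1 (-8.11 to -5.79), Cx3cr1 (-8.35 to -6.05), Fcrls (-6.23 to -5.94), Spp1 (-5.93 to -3.39), Rgs2 (-5.87 to -4.77) and S100a4 (-5.93 to -5.16), with Ptgs1 the constitutive cyclooxygenase. Glycolysis genes were higher at 24 h in 18 of 20 in KO1, 18 of 20 in KO2, 19 of 20 in KI (camera adjusted p = 3.2e-12, 1.3e-10, 9.9e-15, adjusted p = 0.0550, 0.00888, 0.00320 with an estimated correlation), and proteasome and ubiquitin genes in 28 of 30 in KO1, 28 of 30 in KO2, 30 of 30 in KI (camera adjusted p = 5.2e-17, 1.3e-09, 1.5e-12, adjusted p = 0.0900, 0.0558, 0.0157 with an estimated correlation). Cell cycle genes were lower in 34 of 42 in KO1, 22 of 30 in KO2, 27 of 41 in KI (camera adjusted p = 2.0e-09, 9.1e-04, 3.4e-04, adjusted p = 0.177, 0.00208, 0.00126 with an estimated correlation). Over all genes tested, edgeR called 7767, 7641 and 8450 genes at 6 h and 5743, 6401 and 7337 at 24 h in KO1, KO2 and KI.

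In KO1, with 3 cultures per genotype, few single genes passed the test besides Becn1. At rest Procr, the endothelial protein C receptor gene, rose (2.05 ± 0.34, adjusted p = 0.0333, higher in 3 of 3 KO cultures), as did the uncharacterised transcript 1810033B17Rik (2.85 ± 0.43, adjusted p = 0.0143), which makes 3 calls with Becn1 of 13693 genes tested. At 6 h Serpinb2, the plasminogen activator inhibitor 2 gene, rose (2.46 ± 0.39, adjusted p = 0.0270), as did AC116996.1 (1.59 ± 0.26, adjusted p = 0.0283), each higher in 3 of 3 KO cultures, and at 24 h Becn1 was the 1 call. No member of the inflammatory list was called over all genes at rest, where its median log2 fold change was 0.70 over 40 measured genes. With 8 higher adjusted over the list alone, the list had camera adjusted p = 7.1e-16 and adjusted p = 0.112 with an estimated correlation. Repeats 1 and 2 of culture S37 stand apart in the list's member Il12b, at 171 and 219 CPM. Its repeat 3, at 36.3 CPM, lies within the 9.60 to 45.3 of the other resting KO libraries. Neutrophil markers had a median of 1.45 over 13 genes at rest. With 8 higher adjusted over the list alone, the list had camera adjusted p = 6.9e-10 and adjusted p = 0.101 with an estimated correlation. Type I interferon-stimulated genes had 0.67 over 41 genes and interferon-gamma targets 0.88 over 35. With no call adjusted over the list alone, type I interferon-stimulated genes had camera adjusted p = 4.4e-09 and adjusted p = 0.659 with an estimated correlation. With 2 higher adjusted over the list alone, interferon-gamma GTPases and targets had camera adjusted p = 7.1e-16 and adjusted p = 0.179 with an estimated correlation. The mean log2 CPM of the type I list was 5.31, 3.28 and 7.00 in WT cultures S33 to S35 and 7.25, 4.47 and 6.86 in KO cultures S36 to S38, so the genotypes overlap and the range within WT (3.72) exceeds the difference between their means. Cell cycle genes had -0.39 over 42 genes, and none of these KO1 list calls holds with an estimated correlation. With 1 lower adjusted over the list alone, the list had camera adjusted p = 1.1e-08 and adjusted p = 0.265 with an estimated correlation. At an unadjusted p under 0.05, 846, 655 and 948 genes differed at 0 h, 6 h and 24 h, where 685 would by chance. By other settings the calls at 0 h, 6 h and 24 h were 39, 5, 4 with DESeq2, 264, 35, 78 with voom on single libraries and 154, 72, 86 in edgeR without a filter, but 0, 0, 3 with only the 2 groups compared. The voom fit blocks on culture number over all times at a consensus correlation of 0.0872, so it takes repeats of a culture as nearly independent. Without 1 culture in turn, calls at 0 h, 6 h and 24 h were 0, 0 and 0 (S33), 0, 0 and 0 (S34), 40, 1 and 4 (S35), 0, 1 and 0 (S36), 1, 4 and 8 (S37), 0, 0 and 0 (S38). The call of Procr is lost (adjusted p = 0.818 without S33, 0.427 without S34, 0.0711 without S36, 0.0696 without S37 and 0.211 without S38), as is that of Serpinb2 (0.607 without S33, 0.454 without S34, 0.106 without S35, 0.155 without S36 and 0.141 without S38) and AC116996.1 (0.607 without S33, 0.186 without S34, 0.411 without S36, 0.0523 without S37 and 0.399 without S38, and 0.0691 without the sample of conflicting labels). That of 1810033B17Rik is lost too (0.113 without S33, 0.245 without S34, 0.0528 without S36, 0.0696 without S37 and 0.0782 without S38). Without S36 the log2 fold change of Serpinb2 at 6 h was 1.68. With only the 2 groups compared each of the 4 is lost (adjusted p = 0.270 for Procr, 1 for Serpinb2, 0.192 for AC116996.1 and 0.459 for 1810033B17Rik). On data simulated with the counts, spread and 3 cultures of KO1 a 4-fold change was recovered in 87.9% of genes and a 2-fold change in 32.8%.

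**Figure D2:**
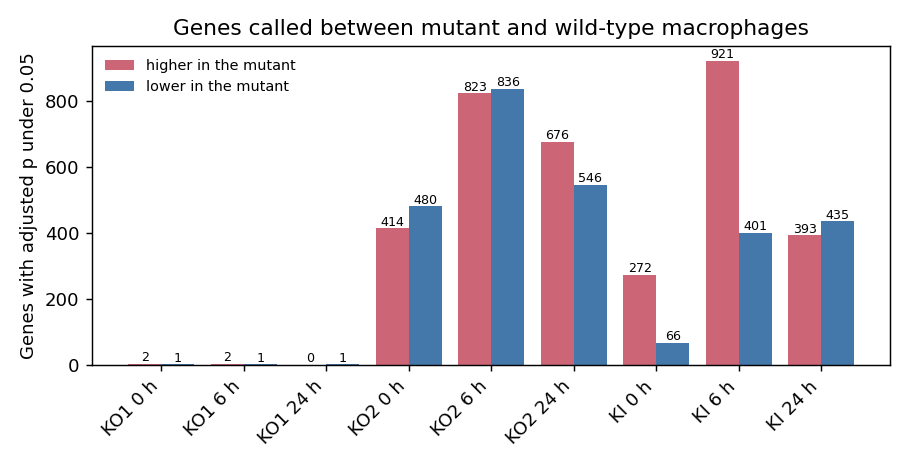
Number of genes with an adjusted p under 0.05 that are higher (red) or lower (blue) in the mutant than in WT, per cohort and time, from edgeR. KO1 has 3 cultures per group, KO2 8 libraries (7 in WT at 24 h) and KI 6.

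Resting KO2 knockout macrophages expressed interferon-induced genes at a higher level than WT. Of 40 measured type I interferon-stimulated genes 38 rose, among them Irf7 (2.88 ± 0.15), Oasl1 (2.02 ± 0.15) and Ms4a4c (3.28 ± 0.25), with Irf7 a master transcription factor of interferon responses. With 40 higher adjusted over the list alone, the list had camera adjusted p = 6.7e-74 and adjusted p = 5.6e-07 with an estimated correlation. Interferon-gamma GTPases and targets rose in 21 of 35, with Ly6a (2.77 ± 0.17), Il18bp (2.08 ± 0.14) and Iigp1 (3.09 ± 0.42). With 24 higher adjusted over the list alone, the list had camera adjusted p = 2.1e-29 and adjusted p = 2.0e-04 with an estimated correlation. The chemokine gene Ccl5 (3.61 ± 0.20, adjusted p = 6.7e-22) and the homing receptor Ccr7 (2.90 ± 0.61) were also among the strongest to rise. Each of Irf7, Oasl1, Ms4a4c, Ly6a, Il18bp, Iigp1 and Ccl5 was higher in 8 of 8 KO libraries. Antigen presentation followed: 13 of 20 MHC class I genes rose and 1 fell, with H2-Q6 (2.69 ± 0.16) and H2-Q7 (2.14 ± 0.17), and 9 of 14 MHC class II and co-stimulation genes rose, with H2-Ab1 (2.60 ± 0.18), H2-Eb1 (2.49 ± 0.18) and H2-Aa (2.47 ± 0.20). With 16 higher and 1 lower adjusted over the list alone, MHC class I antigen presentation had camera adjusted p = 5.8e-25 and adjusted p = 6.7e-04 with an estimated correlation. With 9 higher adjusted over the list alone, MHC class II and co-stimulation had camera adjusted p = 1.6e-13 and adjusted p = 1.5e-04 with an estimated correlation. In the cGAS-STING and RIG-I pathway 6 of 17 rose, with Zbp1 (1.40 ± 0.17) and Dhx58 (0.89 ± 0.11), nucleic acid sensors that are themselves interferon-induced. With 8 higher adjusted over the list alone, the list had camera adjusted p = 5.1e-09 and adjusted p = 6.7e-04 with an estimated correlation. Endoplasmic reticulum chaperones fell in 12 of 22, with Hspa5 (-0.72 ± 0.11), Hsp90b1 (-0.59 ± 0.08) and Sdf2l1 (-0.67 ± 0.12). With 12 lower adjusted over the list alone, the list had camera adjusted p = 5.9e-11 and adjusted p = 7.6e-07 with an estimated correlation. Cytosolic ribosomal protein genes fell in 36 of 47, with Rps24 (-0.80 ± 0.14), Rps4x (-0.71 ± 0.11) and Rpl7 (-0.53 ± 0.10), and mitochondrially encoded genes in 10 of 12, with mt-Nd4 (-0.68 ± 0.13) and mt-Cytb (-0.85 ± 0.16). With 44 lower adjusted over the list alone, cytosolic ribosomal proteins had camera adjusted p = 5.4e-26 and adjusted p = 0.0711 with an estimated correlation. With 10 lower adjusted over the list alone, mitochondrially encoded genes had camera adjusted p = 1.4e-09 and adjusted p = 0.0711 with an estimated correlation. Outside these lists Gdf3 (-1.64 ± 0.20), a TGF-beta family ligand, Colec12 (-1.46 ± 0.20), a scavenger receptor, and the glutamine synthetase gene Glul (-1.12 ± 0.12) were among those that fell furthest. Monocyte markers rose at rest in 2 of 8, namely Ccr2 (1.17 ± 0.20) and Ly6c2 (2.09 ± 0.62), higher in 8 and 7 of 8 KO libraries, and of 4 neutrophil markers 1 did, Csf3r (0.40 ± 0.11). With 3 higher adjusted over the list alone, monocyte markers had camera adjusted p = 0.00640 and adjusted p = 0.0105 with an estimated correlation. With 2 higher adjusted over the list alone, neutrophil markers had camera adjusted p = 0.0416 and adjusted p = 0.0456 with an estimated correlation. The call of Ly6c2 is lost without a filter (adjusted p = 0.0617) or with sums in threes (adjusted p = 0.0873) and that of Csf3r without a filter (adjusted p = 0.0616) or with sums in threes (adjusted p = 0.113). EdgeR called 894 of 10794 genes, 414 higher and 480 lower in 8 KO than in 8 WT libraries. All KO2 WT libraries expressed Xist, the RNA of the inactive X chromosome (70.0 to 340 CPM), and all KO libraries expressed the Y-linked Ddx3y (5.33 to 24.3 CPM) with at most 1.62 CPM of Xist, so genotype and sex cannot be told apart in KO2 at any time. Satellite-like repeat transcripts took 5.73% (SD 3.42) of counts in resting KO and 2.87% (SD 1.67) in WT libraries. With libraries summed in threes by replicate number, in case these are repeats of a culture, 564 genes are called, 530 of them shared.

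**Figure D3:**
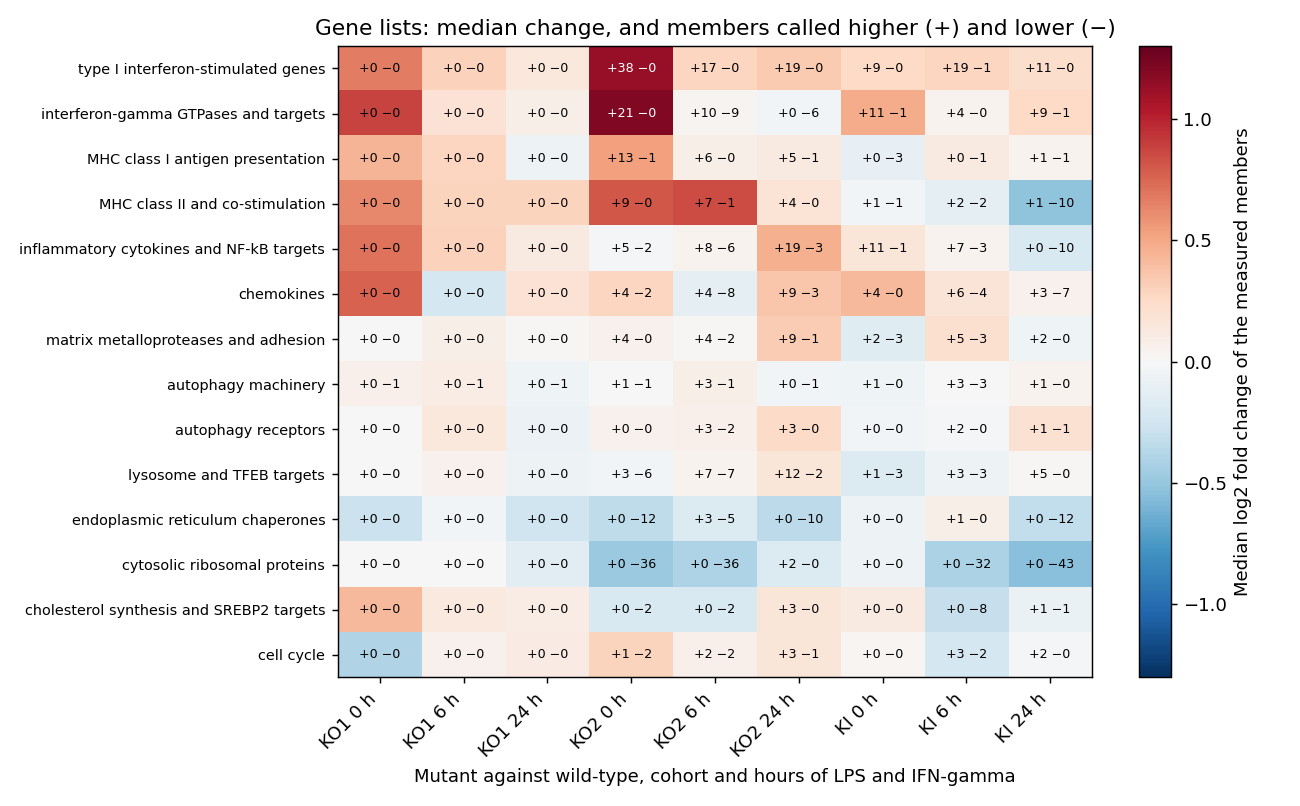
Median log2 fold change (color) of the measured members of 14 lists in each mutant against WT comparison, with the number of members called higher (+) and lower (−) over all genes tested.

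**Figure D4:**
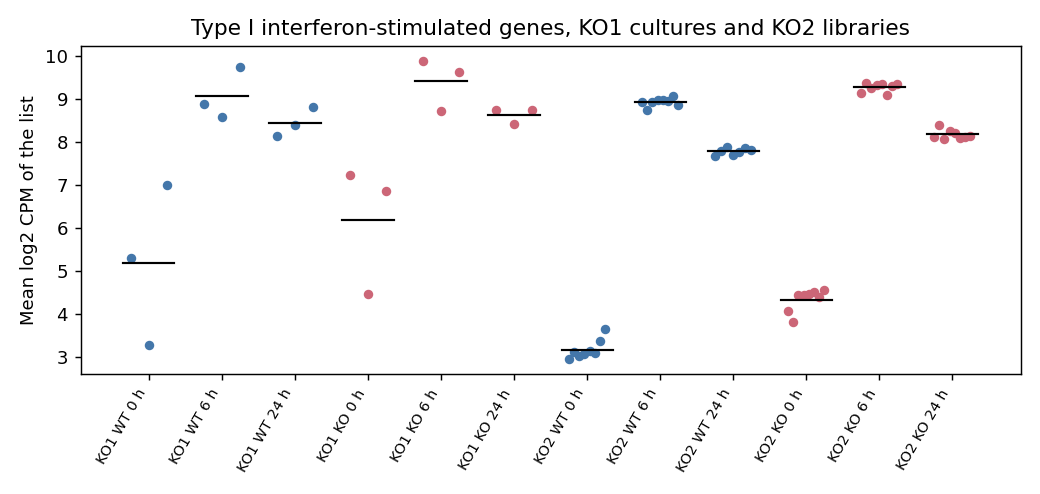
Mean log2 CPM of the type I interferon-stimulated list in each KO1 culture and KO2 library. Bars are group means, blue is WT and red is KO. Resting KO2 KO libraries lie above resting WT, and the 3 resting WT cultures of KO1 spread over 3.72 on the log2 scale.

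At 6 h of stimulation, KO2 knockout macrophages differed from WT in macrophage identity and immediate-early genes and in single receptor and antigen presentation genes. The scavenger receptor Marco fell by 3.44 on the log2 scale (SE 0.23, adjusted p = 7.6e-18, lower in 8 of 8 KO libraries), beside Nptx1 (-2.44 ± 0.43), Trim47 (-1.87 ± 0.27) and Lyz1 (-1.65 ± 0.21). Macrophage identity genes fell in 10 of 19 and rose in 2, with Fcgr3 (-1.21 ± 0.13) and C1qc (-0.69 ± 0.12), an Fc receptor and a complement C1q chain. With 3 higher and 11 lower adjusted over the list alone, the list had camera adjusted p = 1.6e-07 and adjusted p = 0.00816 with an estimated correlation. The monocyte marker Plac8 rose in the same comparison, and bulk counts do not part a change in the share of cells from one within each cell. Of 29 phagocytic and scavenger receptors 15 fell and 3 rose, with Fcgr2b (-1.01 ± 0.11) among the former. With 5 higher and 16 lower adjusted over the list alone, the list had camera adjusted p = 7.0e-05 and adjusted p = 0.0797 with an estimated correlation. MHC class II and co-stimulation rose in 7 of 14 and fell in 1, with H2-Aa (1.75 ± 0.19), H2-Eb1 (1.62 ± 0.16) and H2-Ab1 (1.35 ± 0.16). With 8 higher and 1 lower adjusted over the list alone, the list had camera adjusted p = 7.9e-05 and adjusted p = 0.0797 with an estimated correlation. H2-Q6, H2-Q7, Ly6a, the apolipoprotein L gene Apol7c and the TNF family ligand Tnfsf15 were among the strongest to rise (2.29 ± 0.14, 1.99 ± 0.16, 2.16 ± 0.16, 4.15 ± 0.29 and 1.90 ± 0.18). As a list, type I interferon-stimulated genes rose in 17 of 40, with Ifi44 (1.13 ± 0.12), Slfn1 (0.94 ± 0.14) and Isg20 (0.83 ± 0.13). With 18 higher adjusted over the list alone, the list had camera adjusted p = 7.0e-05 and adjusted p = 0.30 with an estimated correlation. The inflammatory list, with a median of 0.04 and a test direction of down, went both ways, 8 higher and 6 lower of 38, with Il12a (1.77 ± 0.20) and Il1a (1.26 ± 0.14), and the chemokine list too, with 4 higher and 8 lower of 20, with Cxcl1 at 1.86 ± 0.21 and Ccl7 at -1.41 ± 0.13. With 8 higher and 10 lower adjusted over the list alone, inflammatory cytokines and NF-kB targets had camera adjusted p = 0.824 and adjusted p = 0.874 with an estimated correlation. With 4 higher and 8 lower adjusted over the list alone, chemokines had camera adjusted p = 0.0283 and adjusted p = 0.346 with an estimated correlation. Immediate-early genes fell in 6 of 14, with Ier2 (-0.94 ± 0.10) and Fos (-0.66 ± 0.12), genes that also respond to handling. With 7 lower adjusted over the list alone, the list had camera adjusted p = 2.7e-06 and adjusted p = 0.00816 with an estimated correlation. Ribosomal protein genes fell in 36 of 47, with Rps27a (-0.82 ± 0.17) and Rpl3 (-0.72 ± 0.13). With 38 lower adjusted over the list alone, the list had camera adjusted p = 2.7e-13 and adjusted p = 0.315 with an estimated correlation. Of 16 autophagy receptors 3 rose and 2 fell: the cargo receptors Sqstm1 (0.75 ± 0.14), Calcoco1 (0.90 ± 0.20) and Nbr1 (0.65 ± 0.15) were higher, and the mitophagy receptor Bnip3 (-0.51 ± 0.13) and Tax1bp1 (-0.23 ± 0.08) lower. With 3 higher and 3 lower adjusted over the list alone, the list had camera adjusted p = 0.676 and adjusted p = 0.761 with an estimated correlation. EdgeR called 1659 of 10794 genes, 823 higher and 836 lower (n = 8 libraries per genotype). The call of Tax1bp1 is lost without a filter (adjusted p = 0.517), with only the 2 groups (adjusted p = 0.102), with replicate number as a block (adjusted p = 0.0633) or with sums in threes (adjusted p = 0.352).

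After 24 h, KO2 knockout macrophages held more RNA of many inflammatory genes and of some chemokines than WT. Inflammatory cytokines and NF-kB targets rose in 19 of 38 and fell in 3. With 22 higher and 3 lower adjusted over the list alone, the list had camera adjusted p = 1.8e-16 and adjusted p = 1.1e-06 with an estimated correlation. Among the strongest were Il10 (3.70 ± 0.24), an anti-inflammatory cytokine, Il1a (3.18 ± 0.16) and Il6 (2.81 ± 0.17), each higher in 8 of 8 KO libraries with adjusted p of 4.5e-19 or less. Of 20 chemokines 9 rose and 3 fell, with Ccl3 (3.30 ± 0.15), Cxcl1 (3.19 ± 0.27), Ccl4 (2.70 ± 0.13) and Cxcl2 (2.28 ± 0.17), which attract monocytes or neutrophils. With 10 higher and 4 lower adjusted over the list alone, the list had camera adjusted p = 2.4e-06 and adjusted p = 0.0537 with an estimated correlation. Tnfsf15 (3.35 ± 0.31) and Inhba (2.95 ± 0.15), the activin A subunit, rose as well. Matrix metalloproteases and adhesion genes rose in 9 of 22 and fell in 1, with Spp1 (2.05 ± 0.17), Mmp12 (1.89 ± 0.14) and Sdc1 (1.22 ± 0.10). With 10 higher and 1 lower adjusted over the list alone, the list had camera adjusted p = 2.9e-08 and adjusted p = 0.00202 with an estimated correlation. Lysosome and TFEB target genes rose in 12 of 46 and fell in 2, with Atp6v0d2 (2.93 ± 0.20), Gpnmb (1.79 ± 0.13) and Gla (0.76 ± 0.09). With 16 higher and 3 lower adjusted over the list alone, the list had camera adjusted p = 7.3e-07 and adjusted p = 0.0942 with an estimated correlation. Type I interferon-stimulated genes rose in 19 of 40, with Oasl1 (1.06 ± 0.13), Isg20 (1.02 ± 0.14) and Ifi44 (1.01 ± 0.12), while interferon-gamma targets fell in 6 of 35, with Cxcl9 (-0.70 ± 0.13) and Serpina3g (-0.68 ± 0.13). With 21 higher adjusted over the list alone, type I interferon-stimulated genes had camera adjusted p = 1.8e-09 and adjusted p = 0.0942 with an estimated correlation. With 1 higher and 7 lower adjusted over the list alone, interferon-gamma GTPases and targets had camera adjusted p = 0.230 and adjusted p = 0.706 with an estimated correlation. Endoplasmic reticulum chaperones fell in 10 of 22, with Calr (-1.17 ± 0.16), Sdf2l1 (-0.88 ± 0.12) and Pdia3 (-0.68 ± 0.10). With 13 lower adjusted over the list alone, the list had camera adjusted p = 2.0e-07 and adjusted p = 4.3e-05 with an estimated correlation. Marco (-2.53 ± 0.22), the sterol hydroxylase Cyp27a1 (-2.00 ± 0.36), the matrix protein Tnc (-2.27 ± 0.52) and the focal adhesion protein Zyx (-1.88 ± 0.21) fell furthest after Xist and Becn1. Autophagy receptors rose in 3 of 16, the cargo receptors Optn (0.95 ± 0.18), Sqstm1 (0.64 ± 0.15) and Tax1bp1 (0.25 ± 0.09). With 4 higher and 1 lower adjusted over the list alone, the list had camera adjusted p = 0.0717 and adjusted p = 0.156 with an estimated correlation. Cell type markers moved in the same comparison: monocyte markers rose in 6 of 8, with Nr4a1 (2.21 ± 0.40), Plac8 (1.28 ± 0.25) and Vcan (0.92 ± 0.19), and neutrophil markers in 2 of 4, namely Mmp8 (1.49 ± 0.14) and Csf3r (0.62 ± 0.11). With 6 higher adjusted over the list alone, monocyte markers had camera adjusted p = 1.2e-04 and adjusted p = 3.7e-04 with an estimated correlation. With 3 higher adjusted over the list alone, neutrophil markers had camera adjusted p = 3.9e-04 and adjusted p = 0.00128 with an estimated correlation. Bulk counts do not part a change in the share of such cells from one within each cell. EdgeR called 1222 of 10794 genes, 676 higher and 546 lower in 8 KO than in 7 WT libraries. The call of Tax1bp1 is lost without a filter (adjusted p = 0.363), with only the 2 groups (adjusted p = 0.0633), with replicate number as a block (adjusted p = 0.0628), with sums in threes (adjusted p = 0.157) or with each library's GC trend removed (adjusted p = 0.124). Mean Tnf at 24 h was 608 CPM in KO and 273 in WT of KO2, but 218 and 242 in KO1. Cxcl9 was at 302 and 499 in KO2, and 903 and 812 in KO1. Mean Il12b was 12.1 in KO and 3.52 in WT of KO2, and 144 (SD 32.8) and 97.6 (SD 86.6) in KO1. None of these KO1 differences was called, and that of Il12b lies within the spread of the WT libraries. WT culture S33, at 201, 202 and 233 CPM, lay above the KO mean, and S34 and S35 lay below it.

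Resting F121A macrophages differed from their littermates in a lysosomal membrane gene, a sorting nexin and a set of inflammatory genes. Lamp1, a major lysosomal membrane protein, averaged 3089 (SD 697) CPM in F121A and 242 (SD 64.0) in WT (log2 fold change 3.62 ± 0.26, adjusted p = 1.9e-13), and the sorting nexin Snx20 27.4 (SD 13) and 3.04 (SD 1.2) CPM (3.16 ± 0.43), both higher in 6 of 6 F121A libraries. Both genes also vary between repeats of 1 KO1 culture: in S33 at 24 h Lamp1 was at 395, 1343 and 1830 CPM and Snx20 at 3.41, 9.24 and 35. Resting WT of KO2 held 3179 (SD 427) CPM of Lamp1, near the F121A mean. With a library preparation score as covariate the fold changes of Lamp1 and Snx20 at rest were 3.63 and 3.16, still called. The mean score hardly differed between the genotypes (1.34 in F121A and 1.29 in WT), so the covariate could move them little. Interferon-gamma GTPases and targets rose in 11 of 35 and fell in 1, with Cxcl9 (2.93 ± 0.50), Gbp2 (1.36 ± 0.21) and Ifi47 (0.80 ± 0.12), and Serpina3f rose too (2.65 ± 0.53). With 15 higher and 1 lower adjusted over the list alone, the list had camera adjusted p = 1.6e-16 and adjusted p = 0.0536 with an estimated correlation. Cxcl9 was at 1.47 and 0.840 CPM in F121A replicates 3 and 4, within the WT range of 0.143 to 5.04, and at 20.0 to 35.1 in the remaining ones. Inflammatory genes rose in 11 of 37 and fell in 1, with Cd40 (1.79 ± 0.26), and type I interferon-stimulated genes rose in 9 of 41, with Ifi205 (1.53 ± 0.31) and Ifit1 (0.63 ± 0.12). With 11 higher and 2 lower adjusted over the list alone, inflammatory cytokines and NF-kB targets had camera adjusted p = 9.7e-07 and adjusted p = 0.182 with an estimated correlation. With 12 higher and 1 lower adjusted over the list alone, type I interferon-stimulated genes had camera adjusted p = 1.2e-12 and adjusted p = 0.0536 with an estimated correlation. Ifi205 was higher in 4 of 6 F121A libraries, and its call is lost with only the 2 groups (adjusted p = 0.0569). Il1b (1.29 ± 0.27), Nos2 (2.28 ± 0.48), Il1rn and Irg1 of the inflammatory list rose too, but each was higher in 4 of 6 F121A libraries alone. The call of Il1b is lost with only the 2 groups (adjusted p = 0.108) or with sums in pairs (adjusted p = 0.0511) and that of Nos2 with only the 2 groups (adjusted p = 0.0724). That of Il1rn is lost with only the 2 groups (adjusted p = 0.0564) and that of Irg1 with DESeq2 size factors (adjusted p = 0.0531), with only the 2 groups (adjusted p = 0.207), with replicate number as a block (adjusted p = 0.0503), with sums in pairs (adjusted p = 0.206) or without F121A replicate 5 (adjusted p = 0.0820). Besides Lamp1, the lysosome list fell in 3 of 46, with the cathepsins Ctss (-0.46 ± 0.10) and Ctsd (-0.41 ± 0.10). With 2 higher and 6 lower adjusted over the list alone, the list had camera adjusted p = 2.3e-08 and adjusted p = 0.0700 with an estimated correlation. Neutrophil markers fell in 3 of 7, with S100a8 (-0.93 ± 0.20), as did Lcn2 (-0.84 ± 0.21), Cd200r4 (-0.75 ± 0.12) and Cav1 (-0.65 ± 0.12), the caveolin gene. With 5 lower adjusted over the list alone, the list had camera adjusted p = 3.8e-04 and adjusted p = 0.0167 with an estimated correlation. The call of Lcn2 is lost with only the 2 groups (adjusted p = 0.112). The largest fold changes belong to AC131780.1, AC131780.2, AC131780.3 and AC242409.1 (log2 4.12 to 4.38), counted with satellite-like repeats, which take 34.2% of counts in F121A replicate 5. Without that library they turn to -0.79, -0.97, -0.68 and -0.76, and the total of 338 calls (272 higher and 66 lower of 11500, n = 6 libraries per genotype) becomes 254.

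At 6 h F121A macrophages again held more Lamp1 and Snx20 RNA than their WT, with more Dusp2 and less Cxcl1, Cxcl2 and Cxcl3 RNA. Dusp2, a phosphatase that turns off MAP kinases, rose by 4.37 ± 0.25 (adjusted p = 1.7e-16), beside Snx20 (3.69 ± 0.43), Lamp1 (2.11 ± 0.24) and Snx18 (1.75 ± 0.22), the small GTPase Rac1 (1.77 ± 0.36), the transcription factor Cebpd (1.76 ± 0.23) and the metalloprotease inhibitor Timp1 (1.53 ± 0.16). Each of Dusp2, Snx20, Lamp1, Snx18, Cebpd and Timp1 was higher in 6 of 6 F121A libraries. Lamp1 averaged 1325 CPM in F121A and 313 in WT, against 1508 in WT of KO2 and 491 in WT of KO1. Snx20 averaged 33.7 CPM in F121A and 2.78 in WT, against 93.1 in WT of KO2 and 9.69 in WT of KO1. The neutrophil chemokines Cxcl1 (-1.16 ± 0.16), Cxcl3 (-1.09 ± 0.22) and Cxcl2 (-1.01 ± 0.10) and the IL-12 subunit Il12a (-1.01 ± 0.15) fell, each lower in 6 of 6, while Il10 rose (1.56 ± 0.23). As lists, inflammatory genes rose in 7 and fell in 3 of 37, and chemokines in 6 and 4 of 21. With 8 higher and 3 lower adjusted over the list alone, inflammatory cytokines and NF-kB targets had camera adjusted p = 0.518 and adjusted p = 0.886 with an estimated correlation. With 8 higher and 5 lower adjusted over the list alone, chemokines had camera adjusted p = 0.879 and adjusted p = 0.930 with an estimated correlation. Cholesterol synthesis genes fell in 8 of 23, with Idi1 (-1.25 ± 0.22), Hmgcs1 (-0.83 ± 0.10) and Sc4mol (-0.77 ± 0.11), enzymes of the mevalonate and sterol pathway. With 8 lower adjusted over the list alone, the list had camera adjusted p = 1.5e-05 and adjusted p = 0.00560 with an estimated correlation. Type I interferon-stimulated genes rose in 19 of 41 and fell in 1, with Isg20 (1.19 ± 0.13), Cmpk2 (0.98 ± 0.14) and Rsad2 (0.82 ± 0.13). With 22 higher and 1 lower adjusted over the list alone, the list had camera adjusted p = 5.2e-10 and adjusted p = 0.0889 with an estimated correlation. Macrophage identity genes rose in 9 of 19 and fell in 1, with Fcgr1 (1.18 ± 0.10), C1qc (0.88 ± 0.15) and C1qa (0.62 ± 0.12). With 9 higher and 1 lower adjusted over the list alone, the list had camera adjusted p = 0.0104 and adjusted p = 0.162 with an estimated correlation. Ribosomal protein genes fell in 32 of 47, with Rpl12 (-0.57 ± 0.11) and Rpl5 (-0.55 ± 0.11). With 46 lower adjusted over the list alone, the list had camera adjusted p = 1.8e-20 and adjusted p = 0.236 with an estimated correlation. Immediate-early genes rose in 6 of 14, with Dusp1 (1.47 ± 0.15), Zfp36 (1.15 ± 0.25) and Ier2 (0.90 ± 0.15). With 7 higher adjusted over the list alone, the list had camera adjusted p = 0.00122 and adjusted p = 0.0791 with an estimated correlation. EdgeR called 1322 of 11500 genes, 921 higher and 401 lower (n = 6 libraries per genotype).

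At 24 h F121A macrophages held less IL-12, MHC class II and chaperone RNA than WT and more Ccl7 and Ccl2. Il12b fell by 1.66 on the log2 scale (SE 0.38, adjusted p = 0.00352) and Il12a by 1.44 (SE 0.18), beside H2-M2 (-2.12 ± 0.20), Cxcl3 (-1.40 ± 0.17), Lad1 (-1.43 ± 0.26) and Ctla2b (-1.48 ± 0.16). The chemokines Ccl7 (1.89 ± 0.13, adjusted p = 9.9e-14) and Ccl2 (1.15 ± 0.14) rose, as did Snx20 (3.10 ± 0.36), Rac1 (1.79 ± 0.35), Timp1 (1.37 ± 0.18) and Lamp1 (1.12 ± 0.24). Each of Il12a, H2-M2, Cxcl3, Ccl7, Ccl2, Snx20 and Timp1 lay on its called side of the WT mean in 6 of 6 F121A libraries. MHC class II and co-stimulation fell in 10 of 16 and rose in 1, with H2-DMb1 (-0.82 ± 0.12), H2-Eb1 (-0.69 ± 0.10) and H2-Aa (-0.61 ± 0.09). With 1 higher and 10 lower adjusted over the list alone, the list had camera adjusted p = 2.0e-06 and adjusted p = 0.0180 with an estimated correlation. Endoplasmic reticulum chaperones fell in 12 of 22, with Hyou1 (-0.78 ± 0.15), Sdf2l1 (-0.76 ± 0.13) and Creld2 (-0.57 ± 0.09), and cytosolic heat shock genes in 7 of 15, with Hspa1b (-1.36 ± 0.31). With 17 lower adjusted over the list alone, endoplasmic reticulum chaperones had camera adjusted p = 6.3e-14 and adjusted p = 5.1e-05 with an estimated correlation. With 8 lower adjusted over the list alone, heat shock genes had camera adjusted p = 6.1e-09 and adjusted p = 0.00291 with an estimated correlation. Ribosomal protein genes fell in 43 of 47, with Rps19 (-0.89 ± 0.13). With 46 lower adjusted over the list alone, the list had camera adjusted p = 2.0e-44 and adjusted p = 0.0209 with an estimated correlation. Type I interferon-stimulated genes rose in 11 of 41, with Cmpk2 (1.17 ± 0.14), Rsad2 (1.10 ± 0.13) and Mx1 (0.96 ± 0.12). With 17 higher adjusted over the list alone, the list had camera adjusted p = 1.1e-13 and adjusted p = 0.0199 with an estimated correlation. Endosomal trafficking genes rose in 5 of 31, namely the retromer-associated Snx1 (0.38 ± 0.08), Snx2 (0.40 ± 0.10), Snx5 (0.47 ± 0.09), Snx6 (0.41 ± 0.10) and Vps26a (0.36 ± 0.11). With 5 higher adjusted over the list alone, the list had camera adjusted p = 0.00183 and adjusted p = 0.0209 with an estimated correlation. The call of Snx1 is lost without a filter (adjusted p = 0.0512) and that of Vps26a without a filter (adjusted p = 0.0801) or with sums in pairs (adjusted p = 0.0579). The inflammatory list fell in 10 of 37, with Tnf (-1.40 ± 0.25) and Il1a (-0.80 ± 0.16), and the chemokine list, with a median of 0.06 and a test direction of down, in 7 of 21, with 3 higher, with Ccl3 (-1.32 ± 0.24) among the former. With 12 lower adjusted over the list alone, inflammatory cytokines and NF-kB targets had camera adjusted p = 0.00121 and adjusted p = 0.345 with an estimated correlation. With 4 higher and 8 lower adjusted over the list alone, chemokines had camera adjusted p = 0.888 and adjusted p = 0.931 with an estimated correlation. EdgeR called 828 of 11500 genes, 393 higher and 435 lower (n = 6 libraries per genotype). Tnf was at 594, 733 and 673 CPM in WT replicates 1, 3 and 5, at 157, 186 and 141 in replicates 2, 4 and 6, and at 133 to 173 in F121A. Within WT the Tnf levels thus form 2 separate ranges, and F121A lies near the lower of them. The same WT replicates part in Arg1, at 5.40, 3.39 and 4.26 CPM in 1, 3 and 5 and 56.2, 37.4 and 48.2 in 2, 4 and 6, and in Cxcl9, at 1292, 1463 and 1460 and 983, 1079 and 1073. The labels name no source of this, and the fall of the inflammatory list is measured against both kinds of WT library.

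**Figure D5:**
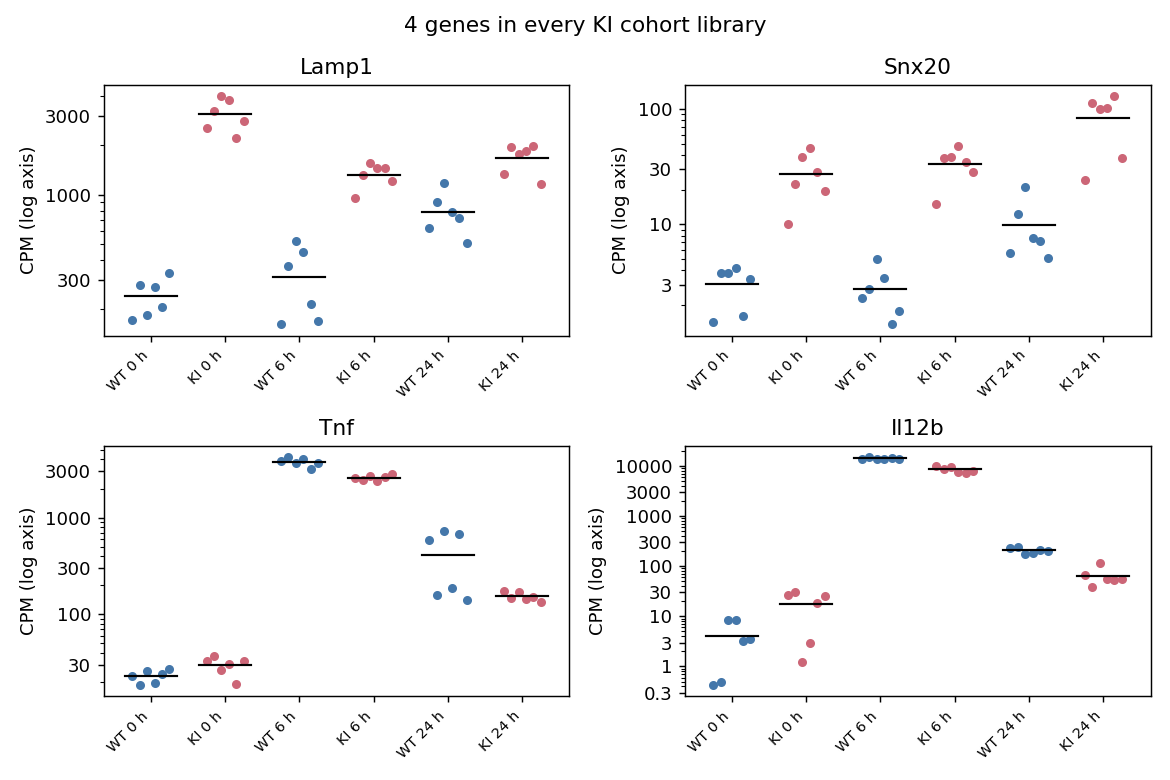
Lamp1, Snx20, Tnf and Il12b in every library of the KI cohort, in CPM on log axes. Bars are group means, blue is WT and red is F121A. Lamp1 and Snx20 are called higher in F121A at all 3 times, and Tnf of WT at 24 h falls into 2 levels.

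The change with stimulation differed between genotypes for 1287 genes in KO2 and 953 in KI. In KO2 the smallest p belonged to Irf7 (-2.71 at 6 h and -3.01 at 24 h), Ccl5 (-3.58 at 6 h and -3.64 at 24 h), Ccl4 (-0.54 at 6 h and 2.05 at 24 h), Il7r (0.39 at 6 h and 1.69 at 24 h) and Ccl3 (0.97 at 6 h and 3.09 at 24 h), given as the log2 fold change of KO over WT minus that at rest. Irf7 and Ccl5 thus differed between genotypes mainly at rest, and the chemokines Ccl3 and Ccl4 and the IL-7 receptor gene Il7r mainly at 24 h. In KI they belonged to Ggta1 (1.54 at 6 h and 0.23 at 24 h), Cyth4 (1.40 at 6 h and 0.56 at 24 h), Ptpn1 (1.29 at 6 h and -0.14 at 24 h), Ccdc90a (-0.20 at 6 h and -1.61 at 24 h) and Il4ra (1.62 at 6 h and 0.71 at 24 h), with Ggta1 a glycosyltransferase, Ptpn1 a tyrosine phosphatase and Il4ra the IL-4 receptor chain. In KO1 edgeR called 0 genes for this difference, with 636 at an unadjusted p under 0.05, and DESeq2 called 17, voom with duplicateCorrelation 201 and edgeR on single libraries 84. The voom fit takes repeats of a culture as nearly independent, and that on single libraries as independent.

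Genes called in KO2 had the same sign in the separate KO1 cohort more often than all genes did, and at 6 h and 24 h not in KI. Of the KO2 calls tested in KO1, 72.3%, 70.2% and 80.9% had the same sign there at 0 h, 6 h and 24 h, against 52.9%, 59.2% and 61.6% of all genes, and in KI 64.2%, 48.0% and 54.9%, against 51.8%, 50.3% and 54.9%. As sets in KO1, genes higher in KO2 had a median log2 fold change of 0.41 (camera p = 5.3e-17, p = 0.0898 with an estimated correlation) at 0 h, 0.24 (camera p = 9.4e-09, p = 0.116 with an estimated correlation) at 6 h and 0.26 (camera p = 3.8e-09, p = 0.0603 with an estimated correlation) at 24 h. Those lower had -0.08 (camera p = 0.0131, p = 0.546 with an estimated correlation), -0.08 (camera p = 0.00948, p = 0.414 with an estimated correlation) and -0.26 (camera p = 1.6e-14, p = 0.00715 with an estimated correlation), so with an estimated correlation the lower set at 24 h alone passes. Called the same way in both cohorts were Becn1 at each time, Procr (2.05 ± 0.34 in KO1 and 0.41 ± 0.12 in KO2) and 1810033B17Rik (2.85 ± 0.43 and 1.58 ± 0.48) at 0 h, and Serpinb2 (2.46 ± 0.39 and 0.95 ± 0.20) at 6 h. In KO2 the call of Procr is lost without a filter (adjusted p = 0.0877) or with sums in threes (adjusted p = 0.152) and that of 1810033B17Rik with sums in threes (adjusted p = 0.0676), and in KO1 all of these calls but that of Becn1 at 24 h are lost with only the 2 groups compared. KO1 cultures part in type I interferon-stimulated genes across genotypes. At rest the list's mean log2 CPM was 5.31, 3.28 and 4.47 in S33, S34 and S37. It was 7.00, 7.25 and 6.86 in S35, S36 and S38, of which S36 and S38 are KO. The shares of equal signs in KO1 thus do not part the knockout from this difference between cultures. The knockout effect differed between KO1 and KO2 for 62, 49 and 35 genes at the 3 times, led by the sex-linked Eif2s3y, Xist, Ddx3y, Kdm5d and Uty (-8.86 ± 0.39, 8.81 ± 0.47, -6.76 ± 0.50, -8.43 ± 0.70 and -2.85 ± 0.40 at 0 h), which mirrors the sexes of the KO2 genotypes, and at 6 h by the complement receptor C5ar1 (1.46 ± 0.22). Between the KO2 knockout and F121A the effect differed for 456, 1434 and 836 genes. At rest Ly6a (3.23 ± 0.21) and Irf7 (2.92 ± 0.20) were raised more by the knockout and Lamp1 (-3.79 ± 0.29) by F121A, on the log2 scale of the difference. For Lamp1 the resting mutants were close, at 3145 CPM in the KO2 knockout and 3089 in F121A, and their WT groups apart, at 3179 and 242. At 6 h Dusp2 (-4.81 ± 0.30), Cyth4 (-2.28 ± 0.16) and Il4ra (-2.85 ± 0.21) leaned to F121A. At 24 h Ccl3 (4.61 ± 0.28), H2-M2 (4.31 ± 0.31), Il1a (3.98 ± 0.23) and Inhba (3.29 ± 0.22) leaned to the knockout. Cohorts were handled as separate sets of libraries, so a difference between them holds the cohort, the sexes and the genotype together.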

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

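The tests of culture differences, sex and library preparation, the preparation score as covariate and the removal of each library's GC trend, were chosen only after the results they address had been seen, and the splits and the GC content test were set before.

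In resting KO2 knockout cells 38 of 40 type I interferon-stimulated genes such as Irf7 were higher, and the mean of the list was 1.16 above WT on the log2 scale, more than the range of 0.70 among WT libraries. A GC trend of single libraries, and library preparation as far as the preparation score measures it, are argued against as the whole cause, since 100% and 100% of the list's called genes stay called higher with each removed. The score moved other genes of this comparison, with 684 of all 894 calls kept. Differences between cultures of a genotype are a candidate explanation, since the list ranged over 3.72 among the 3 resting WT cultures of KO1 and 2.78 among the KO cultures. The labels do not say from how many cultures or mice the KO2 libraries came, so the loss of Becn1, the sexes of the mice and the culture stay open together.

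The 1222 genes called in KO2 at 24 h, Il10 and Ccl3 among them, lie in a comparison of libraries with male and female expression of sex-linked genes. A GC trend of single libraries as the whole cause is argued against, since 88.3% of them stay called the same way with that trend removed. With the preparation score as covariate 99.4% were kept. Its means were close between the genotypes (-0.312 in KO and -0.450 in WT), so it could end few calls and does not decide. Sex cannot be told apart from genotype: in KO1, where both genotypes have the male pattern, the KO2 genes moved the same way with an estimated correlation at a larger p of 0.0603, which misses the threshold. X-linked genes made up 2.34% of the calls and 3.22% of the genes tested (2-sided Fisher's exact test, p = 0.0858), which does not bear on autosomal effects of sex. An effect of the knockout stays open beside it.

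In F121A cells 272, 921 and 393 genes, Lamp1 and Snx20 among them, were higher at 0 h, 6 h and 24 h. A GC trend of single libraries as the whole cause is argued against, since at least 82.0% of them stay called the same way at each time with that trend removed. Their GC content stood at percentile 40.1, 100 and 0.1 of 10000 matched random lists, high at 6 h and low at 24 h. The genes called lower stood at 20.7, 0 and 100. GC content thus parts the calls at 6 h and at 24 h, in opposite directions, so this test does not decide on a GC bias that differs between the times. With the preparation score as covariate at least 95.2% stay called. The calls of AC131780.1, AC131780.2, AC131780.3 and AC242409.1 end (log2 fold changes of 4.12 to 4.38 before, and after it 0.48, 0.55, 0.51 and 0.40). Mean scores of F121A and WT were close at 0 h (1.34 and 1.29), 6 h (-0.767 and -0.695) and 24 h (-0.545 and -0.626). The genotypes thus hardly differ in the score, and as covariate it could end few calls, so the share kept does not decide on library preparation. The score holds 35.7% of the variation between repeats of a KO1 culture, and Lamp1 and Snx20 vary several-fold between such repeats, so other effects of library preparation cannot be told apart from genotype. The called genes' loading on the score stood at percentile 85.9, 98.8 and 84.55 of matched lists, which does not decide. Those percentiles cover only the 84, 372 and 251 of 272, 921 and 393 genes called higher that have a loading, and Snx20 has none. A biological effect of F121A stays open.

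Of 108 values tested for a library that stands apart from its group, 13 did, where chance gives about 1 in 20. The share of satellite-like transcripts stood out in KO1 WT 0 h S35 repeat 2 (1.45%), KO1 KO 0 h S37 repeat 2 (1.14%, with 23644 genes detected), KI WT 0 h replicate 6 (1.01%, with 32.7% of counts in the top 10 genes) and F121A 0 h replicate 5 (34.2%, with 47.1% in the top 10 genes and Lyz2 at 55276 CPM). KO1 KO 0 h S37 repeat 1 had 5550600 counts and Becn1 at 38.9 CPM, KO2 KO 0 h replicate 5 had 8780900 counts, and KO2 KO 6 h replicate 5 had 11846000 counts and 17964 genes detected. The change with time differed between genotypes for 1287 genes in KO2 and 953 in KI. The genotype effect differed between KO1 and KO2 for 62, 49 and 35 genes and between KO2 and KI for 456, 1434 and 836 at 0 h, 6 h and 24 h.

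Other splits of the same samples were refitted with the groups compared alone, each KO2 and KI library taken as independent. If several libraries came from 1 culture, these splits do not give the chance level between cultures. In KO2, 1 of 100 splits, the real one, gave as many calls in each of the 6 comparisons, so a random assignment of single libraries can be excluded: 772, 1320 and 1397 for genotype against 624, 3 and 2 at the highest, 6685 and 6005 for time against 4695 and 3334, and 1287 for genotype by time against 123. In KI the real split was again 1 of 100, so the same can be excluded there: 314, 1352 and 631 against 0, 105 and 6, 7910 and 6928 against 0 and 0, and 953 against 29. In KO1 the 10 splits are too few for a share under 0.05. There as many calls came from 10, 10 and 2 of the splits for genotype (0, 0 and 3 calls, highest other 1055, 1783 and 161), from 1 and 1 for time (6835 and 5523, highest other 0 and 0) and from 10 for genotype by time (0, highest other 823). The split of S33, S34 and S37 against S35, S36 and S38 gave the highest counts for genotype and genotype by time. Its 161 calls at 24 h, many times the 3 of the real split, point to a structure of the cultures that crosses the genotypes. The type I interferon-stimulated list parts the same cultures. Its mean log2 CPM in S33, S34 and S37 was 3.28 to 5.31 at 0 h, 8.60 to 8.90 at 6 h and 8.15 to 8.41 at 24 h. In S35, S36 and S38 it was 6.86 to 7.25, 9.62 to 9.89 and 8.75 to 8.82.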

How the results depend on the processing

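Leave-outs of single KI libraries, sums in threes and pairs, the GC trend, the preparation score and the culture pairs were chosen after seeing the data. Of 208 recomputed counts, shares and list totals, 161 kept within bounds, 47 moved and 0 reversed. A count of calls was taken as kept within 1.5-fold of its value, and a share of signs within its 95% binomial interval, so counts kept here still range widely, as KO1 WT calls at 24 h with 3884 without S33 against 5743 and KI calls at 0 h with 248 (sums in pairs) to 471 (no filter) against 338. Of 5272 recomputed values of named genes, 5136 kept direction and call, 125 lost and 6 gained a call, and 5 changed sign: AC131780.1, AC131780.2, AC131780.3 and AC242409.1 without F121A 0 h replicate 5 (-0.79, -0.97, -0.68 and -0.76), and Becn1 at 6 h in KI without a filter (-0.00198). KO1 calls at 0 h, 6 h and 24 h were 39, 5, 4 with DESeq2, 154, 72, 86 without a filter, 0, 0, 3 with only the 2 groups, 273, 85, 196 with each library as a unit, and 264, 35, 78 with voom. Without 1 culture in turn they ranged over 0 to 40, 0 to 4 and 0 to 8, and with culture numbers paired across genotypes they were 19 at 0 h and 5 at 24 h. These pairs follow the order of the numbers alone, since the labels give none. Calls of genotype by time in KO1 were 17 with DESeq2, 45 without a filter, 84 with each library as a unit, which takes repeats of a culture as independent, and 201 with voom. At its consensus correlation of 0.0872 voom takes repeats as nearly independent too. Differences of KO1 and KO2 effects numbered 146, 123 and 71 without a filter, and 96 (0 h) and 83 (6 h) with DESeq2. KO2 calls at 0 h were 564 with libraries summed in threes, which leaves fewer units. Without a filter, 74.1% of KO2 calls had the same sign in KO1 at 6 h and 67.7% in KI at 0 h. With an estimated correlation 81 of the function list tests were called, against 212 at the preset one. Where no construction is named, the cause was not tested. With replicate number as a block, KO2 calls were 906, 1722 and 1236 and KI calls 355, 1392 and 865. With culture number as a block, KO1 calls in WT were 7957 at 6 h and 5994 at 24 h, against 7767 and 5743 without, and none for genotype by time in either. In data simulated with each cohort's counts, spread and units, 1.5-fold changes were recovered in 2.99% of changed genes in KO1, against 50.7% in KO2 and 47.8% in KI, and the shares of depth, culture number and spread in this were not tested apart.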

Other observations

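The tests of mixing, its leave-outs and the tests of replicate numbers in threes and pairs were chosen only after the patterns had been seen.

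Stress and metabolic genes moved in the KO2 knockout as well. At rest ATF4 targets fell in 4 of 20, with the asparagine synthetase Asns (-0.99 ± 0.13) and Trib3 (-0.79 ± 0.20), and p53 targets rose in 5 of 17, with Gdf15 (0.86 ± 0.19) and Pmaip1 (0.90 ± 0.20). With 5 lower adjusted over the list alone, ATF4 targets had camera adjusted p = 1.9e-04 and adjusted p = 0.0212 with an estimated correlation. With 6 higher and 1 lower adjusted over the list alone, p53 targets had camera adjusted p = 0.00582 and adjusted p = 0.0152 with an estimated correlation. At 24 h ATF4 targets rose in 7 of 20 and fell in 2, with Asns (0.79 ± 0.14), Ppp1r15a (0.71 ± 0.11) and Nupr1 (0.67 ± 0.13), so Asns turned between the times. With 10 higher and 2 lower adjusted over the list alone, the list had camera adjusted p = 0.00530 and adjusted p = 0.0942 with an estimated correlation. Gdf15, a stress-induced cytokine, reached 3.55 ± 0.25 at 24 h. Glycolysis genes fell in 9 of 20 at 6 h and rose in 1, with Pgam1 at -1.06 ± 0.16 and Hk2 at 0.70 ± 0.16. With 1 higher and 10 lower adjusted over the list alone, the list had camera adjusted p = 4.3e-04 and adjusted p = 0.290 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes fell in 17 of 45 at 24 h, with Uqcrh (-0.62 ± 0.13) and Atp5d (-0.55 ± 0.08). With 20 lower adjusted over the list alone, the list had camera adjusted p = 1.5e-09 and adjusted p = 0.180 with an estimated correlation. All of this shares the confounding of genotype and sex in KO2.

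Markers of related cell types also moved. In KO2 at 6 h the monocyte marker Plac8 stood at 3.11 ± 0.63. Osteoclast markers in KO2 at 24 h rose in 3 of 7 and fell in 1: Acp5 (1.46 ± 0.14), Ctsk (1.60 ± 0.34) and Atp6v0d2 (2.93 ± 0.20) were higher and the fusion gene Dcstamp (-1.55 ± 0.49) lower. With 3 higher and 1 lower adjusted over the list alone, the list had camera adjusted p = 9.2e-04 and adjusted p = 0.00224 with an estimated correlation. The call of Dcstamp is lost with sums in threes (adjusted p = 0.103). Macrophages express most of these genes too, so they do not mark a cell type alone. In F121A cells at 6 h the iron importer Tfrc fell (-1.01 ± 0.28) and Cp, a ferroxidase (1.10 ± 0.17), rose.

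In resting KO1 cells 60 of 62 genes strongly induced at 6 h and 36 of 36 at 24 h had a higher mean in KO, and Procr alone among them was called. The genes were chosen by a rise in WT of at least 6 on the log2 scale, with at least 300 CPM in stimulated KO. A low level in resting WT thus helped a gene into the set. This favours a higher KO mean in advance, so the counts do not show one by themselves. A candidate explanation of a higher mean is RNA of stimulated cells mixed into resting KO libraries. Each gene's excess would then be 1 fraction of its stimulated level. Of 62 strongly induced genes such as Cxcl9, 53.2% had an excess within 2-fold of the median fraction (0.205% of the 6 h level), and of 36 genes 61.1% for the 24 h level (0.461%). Both lie between the 50% below which mixing was to be excluded and the 80% it was to reach, so mixing and a higher basal level cannot be told apart. KO1 cultures also part across genotypes in type I interferon-stimulated genes, with S35 of WT and S36 and S38 of KO high at rest. Such a difference between cultures could raise the KO mean of induced genes too, and was not tested for these genes. Without each resting library in turn the shares were 50% to 58.1% and 58.3% to 72.2%. They depend on the cultures: without S37 they were 37.1% and 47.2%, and for 6 h 48.4% without S33 and 48.4% without S35, all below that 50%. Without S37 the excess of Il12b goes from 30.5 to 10.3 CPM.

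Several libraries per culture could make libraries with neighbouring replicate numbers alike, which was tested. Libraries with replicate numbers of the same presumed culture correlated more than others in KO2 by 0.0880, and in KI by 0.0851 (1-sided permutation p = 0.0832 and 0.223). Neither passes the threshold, so the number of independent cultures in KO2 and KI stays open. In KI WT at 24 h Tnf and Arg1 part odd from even replicate numbers, so sums in pairs mix both levels. KI calls at 24 h were 911 with sums in pairs and 828 without. These sums therefore cannot stand for cultures there.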
